A study of Homo sapiens with 81 samples.

How the data were processed

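RNA was measured on 81 single-colour (Cy3) Agilent arrays in 80 samples from 5 lung cancer cell lines, in 27 groups of at most 3 samples. Per the labels, RNA was extracted with Trizol and labelled from 45 ng of total RNA with a low-input amplification kit. Per the file headers, Agilent Feature Extraction 10.7.3.1 read the scans, and its processed signal is an intensity with background subtracted and trends across the array removed, not normalized between arrays. Low values of it had been replaced by a surrogate, so changes near background are compressed. The deposited series matrix is on the log2 scale and, from its values, had been normalized between arrays within each run by the authors with an unstated method. Its correlation with the scanner values on the log2 scale across probes was 0.978 to 0.992, 0.981 to 0.989 and 0.969 to 0.985 within arrays of the 3 runs. The scanner files were used for every result, and the series matrix as an alternative.

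There were 2 array designs. The first (64 arrays) held 50599 probes of 34486 named genes and the second (17 arrays, all of the shBRG1_2 samples) 58201 probes of 41896. Names were updated with the RefSeq annotation of GRCh38.p14, used for names only. On the first design 28174 probes matched by accession, 2618 by symbol and 620 by an older symbol, 17273 kept the name in the file, and 1914 had none. On the second these were 31104, 3366, 496, 21728 and 1507. Coordinates are those of the files, on hg19. Probes of near-identical genes (HSPA1A and HSPA1B, CELA3A and CELA3B, CTAG1A, CT45A1, XAGE1A, SPANXB1, VCX2, the PAGE and the MAGE genes) can bind RNA of their relatives, so such a value belongs to the family. The first design was used in 2 runs, one of 55 arrays on 7 slides and one of the 9 H1299 arrays on 5 slides, and the second in a run of 17 arrays on 4 slides. The labels give no batches, and slides come from the file headers. At most 6 probes were saturated on any array, on 2 arrays in all. One H460 GCRA extract had been hybridised a second time, and its 2 arrays were averaged.

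Control spots were dropped, as were spots the scanner software had marked as outliers (0.596% and 0.120% of spots on the 2 designs), and spots of the same probe were averaged. The log2 signal had the 75th percentile of its array subtracted. A gene was represented by its probe with the highest mean signal. It was tested in a fit if that probe was well above background, per the scanner software, on every array of at least 1 group. One linear model per cell line and array design (7 fits, group means only) was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over the genes tested in the fit). A gene was called at an adjusted p under 0.05. This gave 29 comparisons. They were GCRA and COMB against FBS in each line and construct, COMB against GCRA in control cells, shBRG1 against control cells in FBS, and the response of shBRG1 cells minus that of control cells as an interaction. For the 2 contrasts of MYC-amplified with BRG1-mutant lines, the log2 change of each line was the unit. Tables were handled with data.table (version 1.17.8).

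"Measured" means well above background and not saturated on every array of both groups. Where a group was below that on some or all arrays, the fold is a bound ("at least N-fold"). It sets the mean of the brighter group against that of the dimmer group. Arrays of the latter that were not well above background were raised to the lowest signal of any probe well above background on that array, so the fold is no fitted value. Counts written as a power of 10 (4.4e2) are rounded to 2 digits.

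Gene lists were written from general knowledge (17 lists, 389 genes, of which PAGE5, LYZ and HBA1 were not found on the arrays). They held glucocorticoid-induced, retinoic acid-induced, germline and cancer-testis, interferon-stimulated, HDAC inhibitor-induced, MYC target, cell cycle, neuroendocrine and neuronal, epithelial and lung differentiation, mesenchymal, NF-kB and inflammatory, SWI/SNF subunit, drug target and MYC network, glycolysis, cholesterol synthesis, and heat shock and unfolded protein response genes, and markers of blood, endothelial and stromal cells. Each was tested in each comparison with camera (limma) at a preset correlation of 0.01 and again with a correlation estimated from the residuals, with Benjamini-Hochberg over all 493 tests. Of these, epithelial and lung differentiation genes were called in 13 of 29 comparisons, mesenchymal genes in 5, neuroendocrine and neuronal genes in 2, SWI/SNF subunit genes in 5, HDAC inhibitor-induced genes in 6 and blood, endothelial and stromal cell markers in 3. With an estimated correlation epithelial and lung differentiation genes were called in 2 and the other 5 lists in 0.

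Genes were named by a rule. Ranked genes had a symbol, were called, had all arrays of one group beyond all of the other, and were measured. They were the 2 largest rises and 2 largest falls for GCRA against FBS and for COMB against GCRA in each control line and for each treatment against FBS with either construct, and the 5 and 5 largest for shBRG1 in FBS. For COMB against FBS they were at most 10 up and 10 down called in at least 4 of 5 lines, by mean change. For interactions and line type contrasts they were the 5 smallest adjusted p. Added were at most 2 genes per line well above background in one group only, and at most 4 called members per list and comparison. SMARCA4, SMARCA2, MYC, NR3C1, RARA, RARB and DNMT1 were named always. Of the list members the rule gives a part is shown, and Y-linked genes were left out. The comparisons, tests, lists, rule and alternatives were fixed before the data were examined, except for tests of explanations named in the closing section.

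Alternatives were normexp background correction (offset 50) of the raw spot and background signal, quantile normalization, no filter on dim probes, the mean of all probes of a gene, one fit over all arrays of a run, slide as a block in one fit over the run with the repeat array left out, the replicate number as a block, the series matrix, leaving out each sample (or, for the line types, each line), an estimated correlation for the lists, and the first array only of the repeated extract. A count was taken as moved when it differed by over 1.5 times. The size of a response was the root mean square log2 change over the genes tested, less its error. The model was tested on simulated data with the spread of 3 comparisons. For GCRA in H82 control cells it recovered 43.5%, 58.1% and 81.3% of 62, 74 and 64 genes changed by 0.5, 1 and 2 (log2). Of 131 calls among 22436 genes 7 were false. For A549 the shares were 16.5%, 63.8% and 81.1% among 20083, and for H460 shBRG1_2 cells 5.48%, 59.0% and 80.3% among 26198. Rates with many changed genes were not tested. The labels do not explain shBRG1_2 or say if control cells (titled without a construct) carry one. The shBRG1_2 cells had no control on their design, so no difference from control was computed.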

Results

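Gene expression was measured in 5 human lung cancer cell lines, on 81 arrays of 80 RNA samples in 27 groups. By their labels, H82 is a small-cell and H460 a non-small-cell line with amplified MYC. DMS114 (small-cell), A549 and H1299 (both non-small-cell) are labelled BRG1 mutant. BRG1, the product of SMARCA4, is an ATPase of the SWI/SNF chromatin remodelling complex. Cells were kept in medium with fetal bovine serum (FBS) or were treated for 120 h with dexamethasone, a synthetic glucocorticoid, and retinoic acid at 1 µM each (GCRA), or with both together with 0.2 µM Aza and 0.2 µM SAHA, an inhibitor of histone deacetylases (COMB). H82 and H460 were also present with constructs labelled shBRG1 and shBRG1_2, in all 3 conditions. Each group held 3 samples, apart from 2 of H460 shBRG1_2 cells in COMB. The 75th percentile of spot intensity ran from 320 to 749 on the 55 arrays of the first run, from 883 to 1199 on the 9 H1299 arrays and from 326 to 697 on the 17 shBRG1_2 arrays, and 50.4% to 76.8%, 53.3% to 64.7% and 53.2% to 86.9% of probes were well above background. The number of arrays limits the precision. No slide of the first and second runs held more than 1 array of a group, so a difference within a slide has no spread of its own, and values with slide as a block are given instead.

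Changes below are log2 changes ± the standard error of the limma model, with n = 3 per group unless another n is given. For genes named for the size of change, all arrays of one group lay beyond all of the other. Chance gives this for 10% with 3 against 3. Rankings are of measured genes. List counts carry a second pair, adjusted over the list alone, where that pair differed. Camera called 201 of 493 list tests, 35 of them also with an estimated correlation between genes. Beside the other calls named below the p with an estimated correlation is printed. List medians are also given with unmeasured members at their bounds where this moved them, and with slide as a block. The p-values measure only the spread between these samples, which no label ties to separate cultures.

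SMARCA4 itself was lower in both lines with shBRG1. In FBS its change against control cells was -1.10 ± 0.092 in H82 (adjusted p = 4.7e-07) and -2.42 ± 0.081 in H460 (adjusted p = 2.0e-09). In H82 the difference was -1.07 ± 0.092 in GCRA and -1.13 ± 0.092 in COMB, and in H460 it was -2.30 ± 0.081 and -2.16 ± 0.081. The probe lies on chromosome 19 at 11172673 to 11172732 (hg19). On the log2 scale relative to the 75th percentile of each array, SMARCA4 in FBS was 5.77 ± 0.17 (SD) in H82 control and 4.67 ± 0.066 in H82 shBRG1 cells, 5.17 ± 0.067 in H460 control and 2.76 ± 0.075 in H460 shBRG1 cells, and 2.27 ± 0.022 in A549 and 2.07 ± 0.081 in DMS114, in the same run. The shBRG1_2 cells were measured on another array design that held no control cells, so their SMARCA4 level (5.98 ± 0.026 in H82 and 3.93 ± 0.052 in H460 in FBS) had no control to be set against.

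The first question was what dexamethasone with retinoic acid did to each line. In H82 control cells GCRA raised HOTAIRM1, a noncoding RNA of the HOXA cluster, by 8.91 ± 0.12 and NR2F1, an orphan nuclear receptor gene, by 7.62 ± 0.46. PDZRN4 (-4.38 ± 0.11) and the cadherin gene CDH18 (-4.08 ± 0.19) fell most (largest adjusted p of these 4 genes = 9.0e-09). CLC, which encodes galectin-10, and ERICH5 were not well above background on any FBS array and were at least 230-fold higher and higher by at least 6.70 on the log2 scale. Among retinoic acid-induced genes, 11 of the 21 members tested rose, 2 fell and 8 did not pass, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.0023, median log2 change 0.77). The median was 0.69 with slide as a block and 0.50 with unmeasured members at their bounds. CYP26A1, whose product degrades retinoic acid, was at least 14.4-fold (measured on 1 of the 3 dimmer arrays) higher. Among glucocorticoid-induced genes, 10 of the 19 members tested rose, 4 fell and 5 did not pass (camera adjusted p = 0.037, median log2 change 0.53). The median was 0.49 with slide as a block, and adjusted p = 0.52 with an estimated correlation. The call was also lost without FBS 3, GCRA 1 or GCRA 3, with a median of 0.47, 0.52 and 0.50. Of the members, the clock gene PER1 rose (1.25 ± 0.064) and TSC22D3, the glucocorticoid-induced leucine zipper gene, fell (-1.33 ± 0.066). MYC fell (-1.33 ± 0.084). Among MYC target genes 0 of the 30 members tested rose, 23 fell and 7 did not pass, or 0 and 24 adjusted over the list alone (camera adjusted p = 2.1e-09, median log2 change -0.55). The median was -0.51 with slide as a block, and adjusted p = 0.21 with an estimated correlation. They included MYBBP1A (-1.37 ± 0.090) and RRP9 (-1.27 ± 0.087), which serve ribosome synthesis. Of heat shock and unfolded protein response genes, 0 of the 19 members tested rose, 18 fell and 1 did not pass, or 0 and 19 adjusted over the list alone (camera adjusted p = 1.0e-08, median log2 change -0.65). The median was -0.67 with slide as a block, and adjusted p = 0.10 with an estimated correlation. The largest falls were those of CHAC1 (-2.23 ± 0.15), ASNS (-2.20 ± 0.11) and SESN2 (-2.01 ± 0.082), which are targets of ATF4. For glycolysis genes, 14 of the 20 members tested rose, 1 fell and 5 did not pass, or 16 and 1 adjusted over the list alone (camera adjusted p = 0.00015, median log2 change 0.40). The median was 0.42 with slide as a block, and adjusted p = 0.30 with an estimated correlation. In all, limma called 9184 of 22491 genes, 4502 up and 4682 down. Of these 1557 rose and 714 fell at least 2-fold, and 9097 genes were called with slide as a block.

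In H460 control cells the retinoid genes STRA6, a receptor for retinol-binding protein (8.54 ± 0.30), and DHRS3, a retinal reductase (6.87 ± 0.11), rose most with GCRA. The neurotensin receptor gene NTSR1 (-4.52 ± 0.41) and the urokinase gene PLAU (-4.22 ± 0.085) fell most (largest adjusted p = 1.2e-06). SCNN1A, a subunit of the epithelial sodium channel, and PTPRQ were not well above background in FBS and were at least 40.9-fold and at least 18.0-fold higher. Among glucocorticoid-induced genes, 17 of the 21 members tested rose, 0 fell and 4 did not pass (camera adjusted p = 4.5e-19, median log2 change 1.94). The median was 1.90 with slide as a block. TSC22D3 rose by 3.90 ± 0.065, KLF9 by 3.59 ± 0.060 and PDK4 by 3.42 ± 0.22. Among NF-kB and inflammatory genes, 4 of the 15 members tested rose, 11 fell and 0 did not pass (camera adjusted p = 1.0e-07, median log2 change -1.88). The median was -1.94 with slide as a block. The cytokine genes CXCL8 (-3.87 ± 0.12) and IL6 (-2.83 ± 0.089) were among those that fell. Retinoic acid-induced genes moved up, since 10 of the 16 members tested rose, 1 fell and 5 did not pass (camera adjusted p = 1.3e-06, median log2 change 1.02). The median was 1.05 with slide as a block. HDAC inhibitor-induced genes shifted down, as 1 of the 14 members tested rose, 4 fell and 9 did not pass (camera adjusted p = 0.025, median log2 change -0.24). The median was -0.13 with slide as a block, and adjusted p = 0.25 with an estimated correlation. Limma called 5595 of 20560 genes, 3311 up and 2284 down (631 and 497 by at least 2-fold), and 5675 with slide as a block.

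A549 control cells answered GCRA with rises of MAOA, which encodes monoamine oxidase A (6.81 ± 0.068), and of the kidney cadherin gene CDH16 (5.44 ± 0.091). FXYD2, a modulator of the sodium-potassium pump (-5.69 ± 0.16), and the cytokine gene IL11 (-5.60 ± 0.11) fell most, and the largest adjusted p of the 4 was 3.0e-07. SAA1, an acute-phase protein gene, and NSG1 were not well above background in FBS and were at least 299-fold and at least 128-fold higher. Among glucocorticoid-induced genes, 20 of the 21 members tested rose, 0 fell and 1 did not pass (camera adjusted p = 4.1e-17, median log2 change 2.65). The median was 2.60 with slide as a block. ZBTB16 (4.15 ± 0.17) and TSC22D3 (4.0 ± 0.069) had some of the largest rises. Among retinoic acid-induced genes, 13 of the 18 members tested rose, 2 fell and 3 did not pass, or 13 and 3 adjusted over the list alone (camera adjusted p = 2.7e-05, median log2 change 0.73). The median was 0.75 with slide as a block, and adjusted p = 0.24 with an estimated correlation. MYC fell (-0.63 ± 0.088) by its brightest probe, but was at -0.048 and not called as the mean of all its probes. Of MYC target genes 0 of the 30 members tested rose, 26 fell and 4 did not pass, or 0 and 30 adjusted over the list alone (camera adjusted p = 1.6e-10, median log2 change -0.75). The median was -0.72 with slide as a block, and adjusted p = 0.17 with an estimated correlation. Of cell cycle genes, 2 of the 30 members tested rose, 26 fell and 2 did not pass (camera adjusted p = 8.4e-10, median log2 change -0.91). The median was -0.89 with slide as a block, and adjusted p = 0.16 with an estimated correlation. Examples were the replication helicase gene MCM7 (-1.48 ± 0.084) and the mitotic kinase gene AURKB (-1.41 ± 0.12). For NF-kB and inflammatory genes 2 of the 16 members tested rose, 10 fell and 4 did not pass (camera adjusted p = 0.0012, median log2 change -0.75). The median was -0.79 with slide as a block, where the call was lost (adjusted p = 0.11), and adjusted p = 0.18 with an estimated correlation. TNFAIP3, an inhibitor of NF-kB, was among those that rose (2.98 ± 0.13). Interferon-stimulated genes shifted up, as 11 of the 22 members tested rose, 3 fell and 8 did not pass, or 13 and 3 adjusted over the list alone (camera adjusted p = 0.0052, median log2 change 0.66). The median was 0.69 with slide as a block and 0.26 with unmeasured members at their bounds, and adjusted p = 0.19 with an estimated correlation. IFIT1 rose by 3.50 ± 0.14. Cholesterol synthesis genes shifted up (14 up and 2 down of 19, or 15 and 2 adjusted over the list alone; camera adjusted p = 0.00035, median log2 change 0.43). The median was 0.42 with slide as a block, and adjusted p = 0.24 with an estimated correlation. Limma called 8520 of 20098 genes, 4009 up and 4511 down (1.3e3 and 1072 by at least 2-fold), and 10062 with slide as a block.

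In DMS114 control cells GCRA raised CYP26A1 (4.18 ± 0.082) and FAM13A (2.70 ± 0.11) most. Of measured genes it lowered the immediate-early gene EGR1 (-1.43 ± 0.091) and the hedgehog effector GLI1 (-0.91 ± 0.058) most (largest adjusted p = 0.00063). ADGRG2 was at least 4.60-fold higher and MANSC4 at least 4.96-fold lower. The MANSC4 call was lost without FBS 1, FBS 3 or any 1 of the GCRA samples (adjusted p from 0.055 to 0.15). Among glucocorticoid-induced genes, 6 of the 20 members tested rose, 1 fell and 13 did not pass, or 9 and 1 adjusted over the list alone (camera adjusted p = 2.3e-05, median log2 change 0.18), including FKBP5 (1.24 ± 0.065) and KLF9 (1.16 ± 0.060). The median was 0.21 with slide as a block, and adjusted p = 0.24 with an estimated correlation. Among retinoic acid-induced genes 7 of the 20 members tested rose, 1 fell and 12 did not pass, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.00012, median log2 change 0.30), including DHRS3 (1.74 ± 0.10). The median was 0.33 with slide as a block and 0.12 with unmeasured members at their bounds, and adjusted p = 0.11 with an estimated correlation. Limma called 603 of 20304 genes, 396 up and 207 down (51 and 6 by at least 2-fold). With slide as a block it called 1947, with normexp background correction 221 up and 297 down, and when single samples were left out 125 without FBS replicate 1, 134 without FBS replicate 2, 218 without FBS replicate 3, 152 without GCRA replicate 1 and 329 without GCRA replicate 3.

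H1299 control cells had their own run. Of measured genes GCRA raised DHRS3 (3.29 ± 0.18) and ANGPTL4, a lipase inhibitor gene (3.24 ± 0.13), most. The transmembrane collagen gene COL13A1 (-2.54 ± 0.17) and the collagenase gene MMP1 (-2.53 ± 0.17) fell most (largest adjusted p = 0.00021). TSC22D3 was at least 5.12-fold higher, GMPR at least 3.88-fold and CYP26A1 at least 32.4-fold (measured on 1 of the 3 dimmer arrays). Among glucocorticoid-induced genes, 11 of the 21 members tested rose, 0 fell and 10 did not pass, or 11 and 3 adjusted over the list alone (camera adjusted p = 1.6e-10, median log2 change 0.63), for example FKBP5 (2.02 ± 0.13). The median was 0.71 with slide as a block. For retinoic acid-induced genes 3 of the 16 members tested rose, 1 fell and 12 did not pass, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.013, median log2 change -0.043). The median was -0.058 with slide as a block and 0 with unmeasured members at their bounds, and adjusted p = 0.16 with an estimated correlation. The test was upward, as was the mean (0.55), where the median was not. This call was lost without FBS 3 (adjusted p = 0.054, median -0.076). Among MYC target genes, 1 of the 30 members tested rose, 0 fell and 29 did not pass (camera adjusted p = 7.6e-07, median log2 change 0.18). The median was 0.16 with slide as a block, and adjusted p = 0.34 with an estimated correlation. Limma called 576 of 20583 genes, 242 up and 334 down (94 and 1.2e2 by at least 2-fold), and 30 with slide as a block. It called 243 up and 206 down with normexp background correction, 295 up and 262 down with quantile normalization and 292 up and 263 down from the series matrix. When single samples were left out it called 287 without FBS replicate 1, 256 without FBS replicate 2, 1168 without FBS replicate 3, 206 without GCRA replicate 1, 237 without GCRA replicate 2 and 231 without GCRA replicate 3.

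Across the 5 control lines, 55 genes rose and 11 fell with GCRA in at least 4 lines, and 12 rose in all 5. H460 and A549 shared 1281 rising genes, where independent lists of that length would share 610. H82 and H460 shared 912 rising and 570 falling genes (586 and 4.5e2 if independent) and moved 1420 in opposite directions (1064). The size of the response (root mean square log2 change less its error) was 0.793 in A549 (0.774 to 0.834 when each sample was left out), 0.735 in H82 (0.725 to 0.787), 0.594 in H460 (0.539 to 0.640), 0.329 in H1299 (0.275 to 0.398) and 0.226 in DMS114 (0.182 to 0.325). The second question was whether the MYC-amplified lines responded otherwise than the BRG1-mutant lines. With the line as the unit, limma called 0 of 25200 genes for GCRA and 0 for COMB. The smallest adjusted p was 0.9999 for GCRA and 0.52 for COMB. In each, 797 genes passed an unadjusted p under 0.05, a share below the 0.05 that chance alone would give. Response sizes were higher by 0.215 for GCRA in the MYC-amplified lines (exact permutation test over lines, two-sided p = 0.40) and by 0.0633 for COMB (exact p = 0.90). With 10 possible assignments of the lines the smallest p such a test could give was 0.10.

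**Figure D1:**
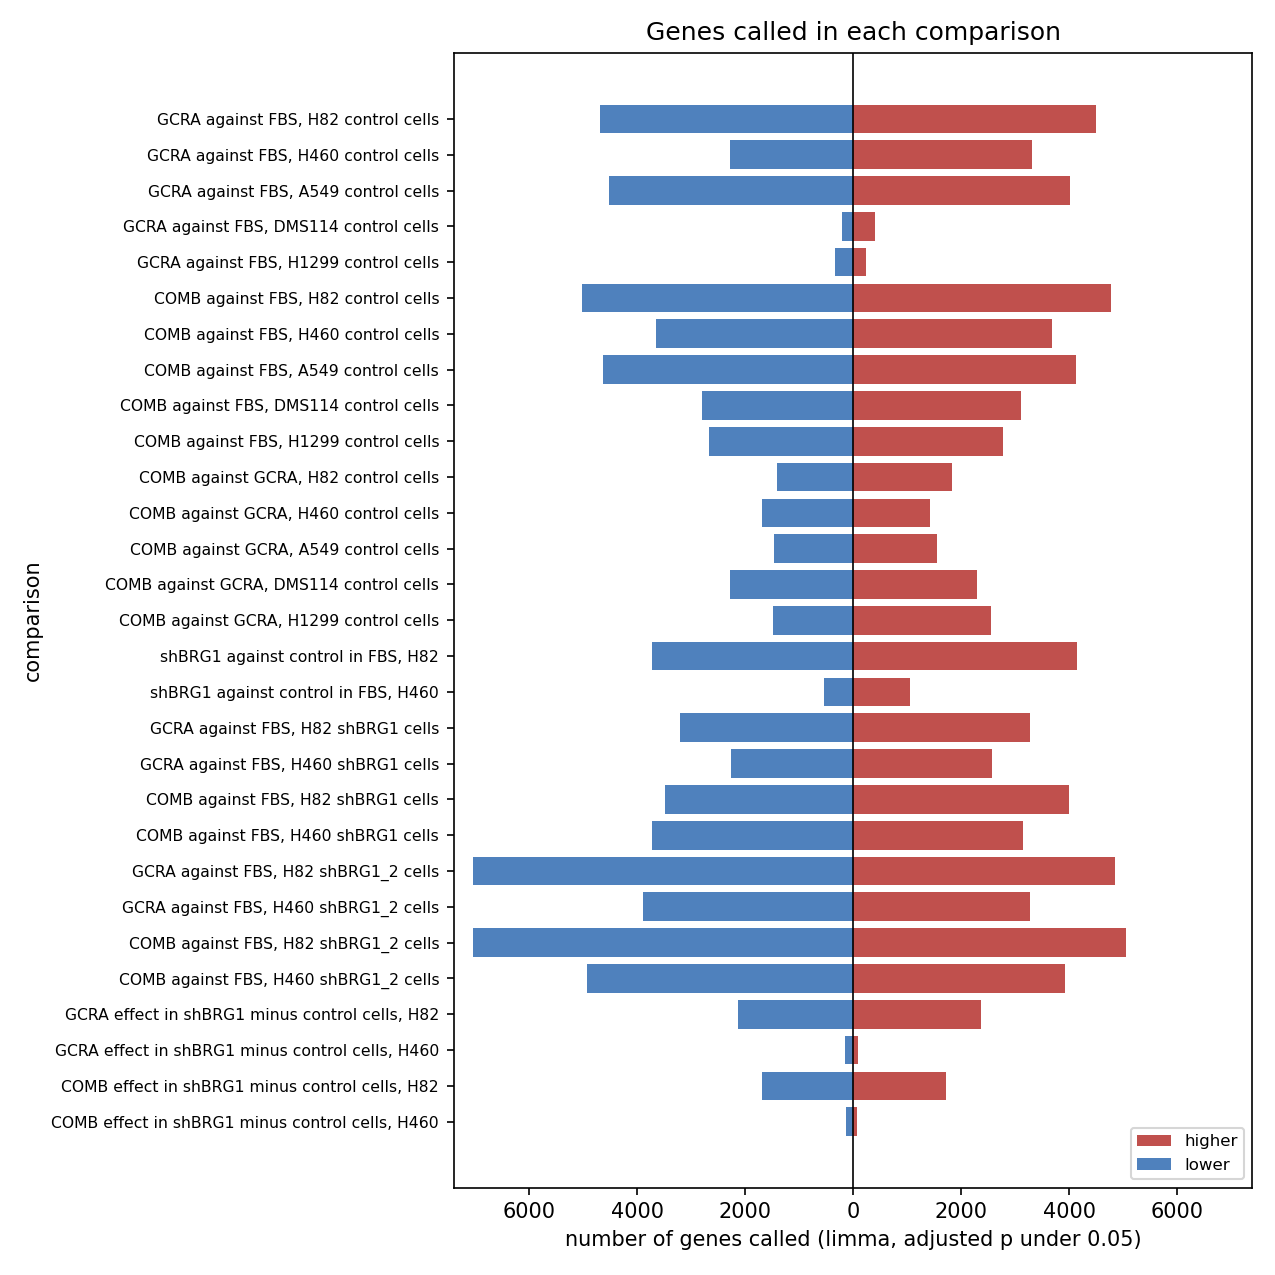
Genes called up and down at adjusted p under 0.05 (x axis, number of genes) in each comparison (y axis). Among the control lines with GCRA H82, A549 and H460 have the longest bars, with 4502 genes up and 4682 down in H82 and 396 up and 207 down in DMS114.

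With COMB against FBS, TERT, which encodes the catalytic subunit of telomerase, fell in all 5 lines (-1.23 in H82, -0.63 in H460, -3.26 in A549, -1.32 in DMS114 and -1.02 in H1299). In at least 4 of 5 lines 544 genes rose and 587 fell (348 and 519 by the criteria for ranked genes). The largest mean rises included the cancer-testis gene CT45A1 (up to 7.18, in H1299), the calcium-binding protein gene S100P (2.38 to 5.72 in 4 lines; -1.26 in H82, not called), GCNA (1.30 to 5.86) and DHRS3 (0.70 to 6.87). Others were the SNARE gene VAMP8 (1.83 to 2.81), HCLS1 (1.21 to 4.66), HOTAIRM1 (0.57 to 8.63 in the 4 lines where it was measured), MAOA (0.33 to 6.45 in 4 lines) and the claudin gene CLDN4 (1.23 to 4.27 in 4 lines; 0.65 and not called in H1299 as the mean of all probes). Besides TERT, the largest mean falls included the histone deacetylase gene HDAC4 (-2.19 to -0.80 in 4 lines), the adhesion receptor gene CD44 (-1.78 to -0.72 in 4 lines) and NFATC1 (-1.67 to -0.98 in 4 lines). Others were MGAT5B (-4.12 to -0.38 in 4 lines), SLCO4A1 (-1.68 to -0.83 in 4 lines), RIBC2 (-1.97 to -0.39 in 4 lines), NKAIN1 (-2.46 to -0.85 in 4 lines), ASNS (-2.56 to -0.31 in 4 lines) and JUN (-3.11 to -0.23 in 4 lines). The JUN call in A549 was lost without FBS 1, 2 or 3 or COMB 1 or 2, with values from -0.19 to -0.24. As the mean of all its probes MGAT5B was at 0.077 in H1299 and not called, and that call was also lost without FBS 1 or 2 or COMB 1, 2 or 3, with values from -0.31 to -0.43. RIBC2 in H460 (-0.47; -0.39 without slide) and NFATC1 in H460 (-1.22; -1.67) and DMS114 (-0.98, unmoved) were not called with slide as a block. In one fit over the run RIBC2 in H460 and NFATC1 in DMS114 were not either (adjusted p = 0.51 and 0.20). Retinoic acid-induced genes were called upward in every line. The list had 14 up and 2 down of 21, or 15 and 2 adjusted over the list alone in H82 (camera adjusted p = 2.2e-05, median log2 change 1.15), 10 up and 0 down of 16 in H460 (camera adjusted p = 1.8e-08, median log2 change 1.61) and 15 up and 0 down of 18, or 16 and 0 adjusted over the list alone in A549 (camera adjusted p = 1.0e-08, median log2 change 0.89). In H82 the median was 1.31 with slide as a block and 0.92 with unmeasured members at their bounds. In H460 the median was 1.63 with slide as a block and 1.36 with unmeasured members at their bounds. In A549 the median was 0.90 with slide as a block, and adjusted p = 0.13 with an estimated correlation. It had 13 up and 1 down of 20 in DMS114 (camera adjusted p = 3.5e-06, median log2 change 0.51) and 11 up and 0 down of 16 in H1299 (camera adjusted p = 2.7e-07, median log2 change 1.55). In DMS114 the median was 0.51 with slide as a block, and adjusted p = 0.074 with an estimated correlation. In H1299 the median was 1.53 with slide as a block and 1.15 with unmeasured members at their bounds. Glucocorticoid-induced genes were called upward in all 5 lines. Here the counts were 10 up and 2 down of 19 in H82 (camera adjusted p = 0.0085, median log2 change 0.38), 19 up and 0 down of 21 in H460 (camera adjusted p = 6.3e-19, median log2 change 1.85) and 20 up and 0 down of 21, or 21 and 0 adjusted over the list alone in A549 (camera adjusted p = 4.4e-16, median log2 change 2.25). For H82 the median was 0.31 with slide as a block, and adjusted p = 0.39 with an estimated correlation. For H460 the median was 1.80 with slide as a block. For A549 the median was 2.16 with slide as a block. They were 11 up and 1 down of 20 in DMS114 (camera adjusted p = 3.1e-06, median log2 change 0.38) and 13 up and 0 down of 21 in H1299 (camera adjusted p = 3.3e-07, median log2 change 0.88). For DMS114 the median was 0.38 with slide as a block, and adjusted p = 0.20 with an estimated correlation. For H1299 the median was 0.85 with slide as a block. Limma called 9778 genes in H82 (4765 up, 5013 down) and 7330 in H460 (3687 up, 3643 down). The other 3 counts were 8748 in A549 (4125 up, 4623 down), 5909 in DMS114 (3106 up, 2803 down) and 5449 in H1299 (2779 up, 2670 down). These counts with slide as a block were 10029, 7545, 10334, 6472 and 2816.

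**Figure D2:**
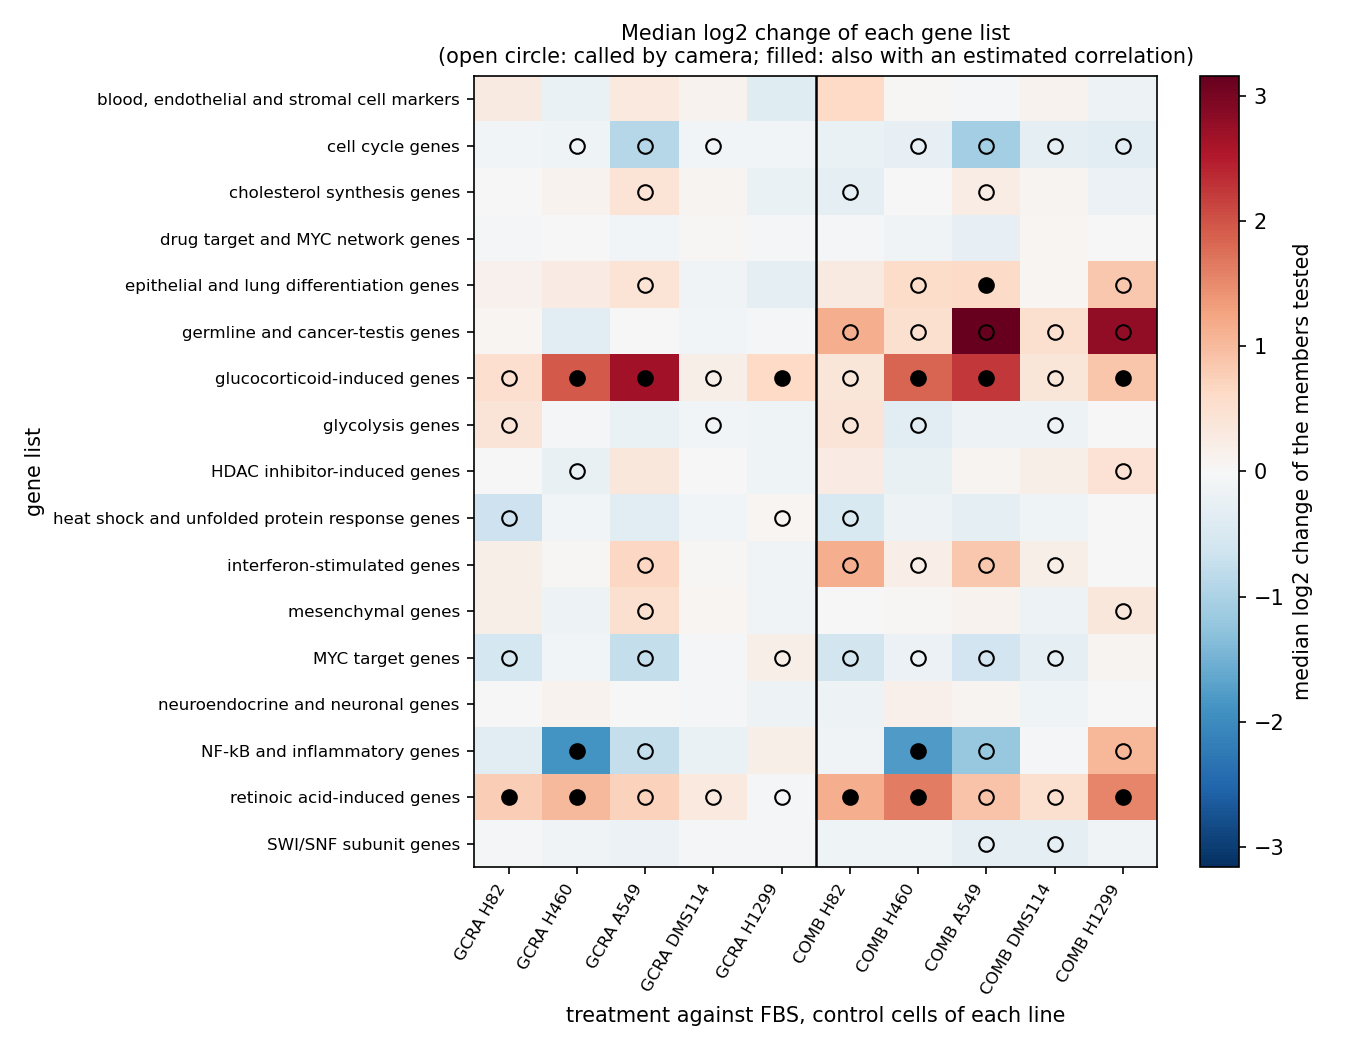
Median log2 change of the members tested of each gene list (y axis; colour scale, log2) with GCRA and with COMB against FBS in the control cells of each line (x axis). Circles mark lists called by camera, filled where also called with an estimated correlation.

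The third question was what Aza and SAHA added to GCRA. Germline and cancer-testis genes, mostly silent outside the testis, were called upward in all 5 lines, also without the filter. The filter drops members dim in every group, so counts and medians lean upward. In H1299 17 of the 24 members tested rose, 0 fell and 7 did not pass, or 18 and 0 adjusted over the list alone (camera adjusted p = 2.3e-15, median log2 change 3.15). The median was 3.24 with slide as a block and 2.16 with unmeasured members at their bounds, and adjusted p = 0.11 with an estimated correlation. In A549 8 of 13 rose, 0 fell and 5 did not pass (camera adjusted p = 7.5e-08, median log2 change 2.82). The median was 2.74 with slide as a block and 2.08 with unmeasured members at their bounds. In H460 8 of 15 rose, 1 fell and 6 did not pass, or 9 and 1 adjusted over the list alone (camera adjusted p = 7.5e-07, median log2 change 1.22). The median was 1.48 with slide as a block and 1.06 with unmeasured members at their bounds. In H82 8 of 18 rose, 0 fell and 10 did not pass (camera adjusted p = 7.7e-07, median log2 change 0.57). The median was 0.71 with slide as a block and 0.19 with unmeasured members at their bounds. In DMS114 7 of 16 rose, 1 fell and 8 did not pass, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0016, median log2 change 0.58). The median was 0.60 with slide as a block and 0.52 with unmeasured members at their bounds, and adjusted p = 0.14 with an estimated correlation. In H82 the largest measured rises over GCRA were TMEM35A (4.42 ± 0.46) and the cancer-testis antigen gene CTAG1A (4.36 ± 0.29), and the largest falls LAD1 (-1.43 ± 0.30) and the retinol-binding protein gene RBP4 (-1.42 ± 0.094). GTSF1, a germ cell gene, was at least 17.6-fold and the caspase gene CASP8 at least 10.9-fold higher. In H460 these were LCN15 (5.10 ± 0.27) and ABCA4 (4.06 ± 0.54), against RAB3B (-2.12 ± 0.11) and IGFBP3 (-1.72 ± 0.083). CTAG1A was at least 130-fold and GTSF1 at least 31.4-fold higher. A549 raised SPANXB1, a sperm protein gene (7.14 ± 0.15), and MROH2A (5.62 ± 0.15) and lowered BMP6 (-2.45 ± 0.090) and HSD11B1, a cortisone reductase gene (-2.39 ± 0.17). CTAG1A was at least 134-fold and PAGE2B at least 93.1-fold higher. In DMS114 APRT, an adenine salvage gene (5.43 ± 0.11), and VCX2 (3.65 ± 0.089) rose, RPS6KA2 (-1.69 ± 0.15) and the spindle checkpoint gene MAD1L1 (-1.55 ± 0.084) fell. XAGE1A was at least 117-fold and PAGE2 at least 92.2-fold higher. H1299 raised the glutathione peroxidase gene GPX1 (7.29 ± 0.13) and MAGEB2 (6.93 ± 0.31) and lowered ADARB2 (-2.02 ± 0.32) and CCN3 (-1.93 ± 0.16). ADARB2 was at -1.88 and not called with slide as a block. The metallothionein gene MT1M was at least 181-fold and FMR1NB at least 99.1-fold higher.

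Several other lists moved with COMB against GCRA. Interferon-stimulated genes rose as a list in H82 (8 up and 0 down of 15, or 9 and 0 adjusted over the list alone; camera adjusted p = 1.4e-06, median log2 change 0.53), for example BST2 (2.37 ± 0.055). The median was 0.46 with slide as a block and 0.38 with unmeasured members at their bounds. They also did in H460 (7 up and 0 down of 23, or 8 and 1 adjusted over the list alone; camera adjusted p = 0.0020, median log2 change 0.12). The median was 0.22 with slide as a block. DMS114 followed (6 up and 0 down of 16, or 7 and 0 adjusted over the list alone; camera adjusted p = 0.0055, median log2 change 0.26). The median was 0.34 with slide as a block, and adjusted p = 0.11 with an estimated correlation. Cholesterol synthesis genes shifted down in H82 (0 up and 10 down of 19; camera adjusted p = 2.9e-08, median log2 change -0.26). The median was -0.29 with slide as a block, and adjusted p = 0.10 with an estimated correlation. Glycolysis genes did in H460 (0 up and 11 down of 20, or 1 and 13 adjusted over the list alone; camera adjusted p = 1.5e-07, median log2 change -0.25), with ALDOC at -1.49 ± 0.11. The median was -0.26 with slide as a block, and adjusted p = 0.17 with an estimated correlation. Cell cycle genes shifted down in all 5 lines. In H1299 0 of the 30 members tested rose, 11 fell and 19 did not pass, or 0 and 15 adjusted over the list alone (camera adjusted p = 3.4e-07, median log2 change -0.36). The median was -0.35 with slide as a block, and adjusted p = 0.15 with an estimated correlation. In H82, H460, A549 and DMS114 6, 8, 8 and 11 of 30 members fell (9 and 16 in the last 2 adjusted over the list alone) and 0 rose. Medians were -0.12, -0.18, -0.15 and -0.22 (-0.14, -0.19, -0.18 and -0.24 with slide as a block), with camera adjusted p of at most 0.0017, but 0.55, 0.36, 0.36 and 0.44 with an estimated correlation. SWI/SNF subunit genes shifted down in DMS114 (0 up and 8 down of 23, or 0 and 10 adjusted over the list alone; camera adjusted p = 0.0034, median log2 change -0.22), where SMARCA4 was among those that fell (-0.39 ± 0.062). The median was -0.22 with slide as a block, and adjusted p = 0.33 with an estimated correlation. Of further lists that shifted up in H1299, 4 are given. Epithelial genes had 11 up and 1 down of 22, or 13 and 1 adjusted over the list alone (camera adjusted p = 2.9e-05, median log2 change 0.70), for example KRT19 (5.16 ± 0.20). The median was 0.55 with slide as a block and 0.63 with unmeasured members at their bounds, and adjusted p = 0.16 with an estimated correlation. NF-kB and inflammatory genes had 10 up and 1 down of 15 (camera adjusted p = 0.00013, median log2 change 0.92), for example MMP1 (4.72 ± 0.17). The median was 0.88 with slide as a block and 0.89 with unmeasured members at their bounds, and adjusted p = 0.16 with an estimated correlation. HDAC inhibitor-induced genes had 9 up and 0 down of 14 (camera adjusted p = 0.00014, median log2 change 0.62), for example DHRS2 (4.86 ± 0.29). The median was 0.65 with slide as a block, and adjusted p = 0.17 with an estimated correlation. Mesenchymal genes had 8 up and 0 down of 18, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00067, median log2 change 0.62), for example SPARC (3.91 ± 0.26). The median was 0.58 with slide as a block, and adjusted p = 0.11 with an estimated correlation. Limma called 3238 genes in H82, 3115 in H460, 3014 in A549, 4569 in DMS114 and 4046 in H1299. Rises of at least 2-fold outnumbered such falls in each, with 527 against 29, 367 against 65, 585 against 149, 389 against 72 and 1403 against 165. The calls with slide as a block were 3897, 4130, 5330, 5229 and 1495. Leaving out single samples moved 4 of the counts, to 2058 without GCRA replicate 3 in H460, 1909 without GCRA replicate 2 in A549, 2917 without COMB replicate 1 in DMS114 and 2686 without GCRA replicate 1 in H1299.

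The fourth question was how shBRG1 cells differed before treatment. H82 cells with shBRG1 had higher NR2F1 (5.01 ± 0.46), the intermediate filament gene VIM (4.87 ± 0.16), the G protein subunit gene GNB4 (4.59 ± 0.24), the selenium carrier gene SELENOP (3.86 ± 0.22) and the germ cell gene SOHLH2 (3.85 ± 0.14) than control cells in FBS. They had lower HSPA6, an inducible HSP70 gene (-3.96 ± 0.087), ARFGEF3 (-3.01 ± 0.14), the neuronal gene STMN2 (-2.99 ± 0.41), PCP4 (-2.94 ± 0.074) and the inhibin gene INHBB (-2.85 ± 0.080). The largest adjusted p of these 10 genes was 5.1e-05. Among heat shock and unfolded protein response genes 0 of the 19 members tested rose, 16 fell and 3 did not pass (camera adjusted p = 4.7e-12, median log2 change -0.80). The median was -0.75 with slide as a block. These included HSPA1B (-2.26 ± 0.11), HSPA1A (-2.01 ± 0.058) and DNAJB1 (-1.87 ± 0.074). Of cholesterol synthesis genes 16 of the 19 members tested rose, 0 fell and 3 did not pass, or 17 and 1 adjusted over the list alone (camera adjusted p = 1.9e-08, median log2 change 0.70). The median was 0.73 with slide as a block, and adjusted p = 0.10 with an estimated correlation. The mevalonate pathway gene MVD rose by 1.19 ± 0.14. Markers of blood, endothelial and stromal cells shifted up alongside, as 4 of the 10 members tested rose, 0 fell and 6 did not pass (camera adjusted p = 0.018, median log2 change 0.58). The median was 0.43 with slide as a block, and adjusted p = 0.12 with an estimated correlation. Those that rose were the stromal genes LUM, DCN, PDGFRB and COL1A1. The call was lost without FBS 1 (median 0.69, adjusted p = 0.057). LUM was at least 59.8-fold higher and DCX, a neuronal gene, at least 30.7-fold. Limma called 7866 of 22491 genes, 4143 up and 3723 down (939 and 624 by at least 2-fold), and 7341 with slide as a block.

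H460 cells with shBRG1 had higher SMOC2 (2.62 ± 0.40), OLFML2A (2.43 ± 0.11), the activin gene INHBA (2.24 ± 0.11), GKN1 (2.11 ± 0.39) and the hyaluronidase gene HYAL1 (1.97 ± 0.12) in FBS. They had lower C10orf90 (-3.43 ± 0.16), the interleukin 7 receptor gene IL7R (-3.25 ± 0.34), ALDH2 (-2.45 ± 0.096) and ADAM12 (-2.34 ± 0.17). SMARCA4 itself was the remaining one of the 5 largest falls. The largest adjusted p of the 9 was 0.0034. CLTRN was at least 4.25-fold higher and CYP1A1, a target of the aryl hydrocarbon receptor, at least 3.31-fold lower. With normexp background correction CYP1A1 was at a log2 change of -0.73 and not called (-2.53 without it), and GKN1 was not called in one fit over the run (adjusted p = 0.067). Glycolysis genes shifted up, as 7 of the 20 members tested rose, 0 fell and 13 did not pass, or 9 and 0 adjusted over the list alone (camera adjusted p = 7.2e-06, median log2 change 0.16). The median was 0.10 with slide as a block, and adjusted p = 0.24 with an estimated correlation. The glucose transporter gene SLC2A3 rose by 1.14 ± 0.095. Among glucocorticoid-induced genes 7 of the 21 members tested rose, 2 fell and 12 did not pass, or 10 and 2 adjusted over the list alone (camera adjusted p = 9.2e-05, median log2 change 0.21). The median was 0.19 with slide as a block, and adjusted p = 0.21 with an estimated correlation. Among NF-kB and inflammatory genes 6 of the 15 members tested rose, 2 fell and 7 did not pass, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.0065, median log2 change 0.30). The median was 0.33 with slide as a block, where the call was lost (adjusted p = 0.24), and adjusted p = 0.16 with an estimated correlation. Without the filter on dim probes the median was 0.058 and the list was not called (adjusted p = 0.12). CHAC1 (-1.32 ± 0.17) and ASNS (-0.81 ± 0.074) were lower. For cholesterol synthesis genes 4 of the 19 members tested rose, 0 fell and 15 did not pass, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.00011, median log2 change 0.19). The median was 0.16 with slide as a block, and adjusted p = 0.35 with an estimated correlation. Limma called 1600 of 20560 genes, 1061 up and 539 down (82 and 130 by at least 2-fold), 2261 with slide as a block and 1052 without FBS replicate 3.

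Treated shBRG1 cells were set against shBRG1 cells in FBS. In H82 shBRG1 cells GCRA raised RRAD (7.15 ± 0.082) and HOTAIRM1 (6.95 ± 0.12) most and lowered CDH18 (-3.32 ± 0.19) and RUNDC3B (-3.18 ± 0.12) most. COMB raised RRAD (6.80 ± 0.082) and CTAG1A (6.33 ± 0.29) and lowered CDH18 (-3.98 ± 0.19) and LUM (-3.34 ± 0.25). Retinoic acid-induced genes rose with both, with 16 up and 1 down of 21 in GCRA (camera adjusted p = 4.5e-09, median log2 change 1.04) and 15 up and 1 down of 21 in COMB (camera adjusted p = 1.0e-08, median log2 change 1.28). With GCRA the median was 1.07 with slide as a block and 0.83 with unmeasured members at their bounds. With COMB the median was 1.30 with slide as a block. Cholesterol synthesis genes fell with both, with 0 up and 16 down of 19, or 0 and 18 adjusted over the list alone in GCRA (camera adjusted p = 2.0e-07, median log2 change -0.44) and 0 up and 17 down of 19 in COMB (camera adjusted p = 2.2e-09, median log2 change -0.62). With GCRA the median was -0.49 with slide as a block, and adjusted p = 0.11 with an estimated correlation. With COMB the median was -0.63 with slide as a block, and adjusted p = 0.078 with an estimated correlation. In H460 shBRG1 cells GCRA raised DHRS3 (6.49 ± 0.11) and the complement gene C3 (5.86 ± 0.22) and lowered the laminin gene LAMB3 (-4.19 ± 0.12) and DCLK1 (-3.95 ± 0.11). COMB raised DHRS3 (6.30 ± 0.11) and C11orf86 (6.17 ± 0.11) and lowered DCLK1 (-4.18 ± 0.11) and LAMB3 (-3.77 ± 0.12). Among glucocorticoid-induced genes of H460 shBRG1 cells, 16 of the 21 members tested rose, 1 fell and 4 did not pass, or 17 and 1 adjusted over the list alone with GCRA (camera adjusted p = 6.6e-19, median log2 change 1.80). The median was 1.81 with slide as a block. Among NF-kB and inflammatory genes 2 of the 15 members tested rose, 11 fell and 2 did not pass, or 3 and 11 adjusted over the list alone (camera adjusted p = 3.2e-08, median log2 change -1.49). The median was -1.39 with slide as a block. Limma called 6490 genes with GCRA and 7482 with COMB in H82 shBRG1 cells, and 4821 and 6869 in H460 shBRG1 cells. With slide as a block the counts were 7346, 8047, 5818 and 8068.

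The fifth question was whether the response differed with shBRG1, tested as an interaction (shBRG1 minus control cells). In H82 the GCRA response differed upward for the heat shock genes HSPA6 (3.42 ± 0.12) and HSPA1A (2.05 ± 0.082) and for RFPL2 (3.0 ± 0.11), and downward for RBP4 (-3.28 ± 0.13) and the ubiquitin ligase gene RFFL (-2.39 ± 0.089). The largest adjusted p of these 5 was 4.8e-09. As the mean of all its probes HSPA6 was at 1.06 and not called. The mean level of HSPA6 was 3.37 ± 0.21 (SD) in FBS and 2.69 ± 0.11 in GCRA in control cells, and -0.60 ± 0.051 and 2.15 ± 0.040 in shBRG1 cells. Of heat shock and unfolded protein response genes, 16 of the 19 members tested differed upward, 0 downward and 3 did not pass (camera adjusted p = 1.2e-15, median log2 change 0.87). The median was 0.85 with slide as a block. Of cholesterol synthesis genes, 0 of the 19 members tested differed upward, 11 downward and 8 did not pass, or 0 and 12 adjusted over the list alone (camera adjusted p = 6.6e-07, median log2 change -0.48). The median was -0.49 with slide as a block, and adjusted p = 0.13 with an estimated correlation. Of glycolysis genes 0 of the 20 members tested differed upward, 5 downward and 15 did not pass, or 0 and 6 adjusted over the list alone (camera adjusted p = 0.0095, median log2 change -0.23). The median was -0.28 with slide as a block, and adjusted p = 0.49 with an estimated correlation. The neuronal gene STMN2 differed upward (3.02 ± 0.58). RARB, a retinoic acid receptor gene, was at least 9.11-fold (measured on 2 of the 3 dimmer arrays) higher with GCRA in shBRG1 cells. In control cells its change was 0.18 ± 0.16 and was not called. The difference was 3.15 ± 0.22 (adjusted p = 5.0e-07), with 1 of 3 arrays not well above background in the shBRG1 FBS and in the control GCRA group. Limma called 4507 genes for the difference, 2376 upward and 2.1e3 downward, and 4594 with slide as a block. With COMB the H82 response differed downward for LRRC17 (-3.42 ± 0.12), the growth factor gene IGF1 (-2.52 ± 0.084), RFFL (-2.42 ± 0.089), RAB17 (-2.39 ± 0.083) and the chemokine receptor gene CXCR4 (-2.35 ± 0.085), with a largest adjusted p of 9.8e-10. Of glycolysis genes 0 of the 20 members tested differed upward, 14 downward and 6 did not pass, or 0 and 15 adjusted over the list alone (camera adjusted p = 2.2e-11, median log2 change -0.56), for example HK2 (-1.36 ± 0.082; not called in one fit over the run). The median was -0.63 with slide as a block, and adjusted p = 0.090 with an estimated correlation. Of heat shock genes 10 of the 19 members tested differed upward, 0 downward and 9 did not pass, or 15 and 0 adjusted over the list alone (camera adjusted p = 2.6e-07, median log2 change 0.47). The median was 0.38 with slide as a block, and adjusted p = 0.12 with an estimated correlation. Of MYC target genes 12 of the 30 members tested differed upward, 1 downward and 17 did not pass (camera adjusted p = 2.0e-05, median log2 change 0.24). The median was 0.17 with slide as a block, and adjusted p = 0.37 with an estimated correlation. Cholesterol synthesis genes (camera adjusted p = 0.00017, median log2 change -0.36) and markers of blood, endothelial and stromal cells (camera adjusted p = 0.011, median log2 change -0.86) differed downward. For cholesterol synthesis the median was -0.30 with slide as a block, and adjusted p = 0.24 with an estimated correlation. For these markers the median was -0.79 with slide as a block, and adjusted p = 0.11 with an estimated correlation. In all 3397 genes were called, 1713 upward and 1684 downward, and 3332 with slide as a block.

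In H460 the interactions called fewer genes. With GCRA the ATF4 targets CHAC1 (3.12 ± 0.25) and SESN2 (1.34 ± 0.11), JDP2 (1.90 ± 0.13) and NGEF (1.45 ± 0.086) differed upward and SGK1, a kinase gene that glucocorticoids induce, downward (-1.22 ± 0.098; largest adjusted p of the 5 = 3.1e-05). CHAC1 was 0.97 ± 0.15 (SD) in FBS and 1.02 ± 0.070 in GCRA in control cells, and -0.35 ± 0.39 and 2.82 ± 0.088 in shBRG1 cells. Of heat shock and unfolded protein response genes 7 of the 19 members tested differed upward, 1 downward and 11 did not pass, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.00012, median log2 change 0.11). The median was 0.12 with slide as a block, and adjusted p = 0.19 with an estimated correlation. Of NF-kB and inflammatory genes 4 of the 15 members tested differed upward, 0 downward and 11 did not pass, or 9 and 2 adjusted over the list alone (camera adjusted p = 3.2e-05, median log2 change 0.33). The median was 0.18 with slide as a block, where the call was lost (adjusted p = 0.14). Of glucocorticoid-induced genes 0 of the 21 members tested differed upward, 3 downward and 18 did not pass, or 0 and 5 adjusted over the list alone (camera adjusted p = 0.0014, median log2 change -0.14). The median was -0.011 with slide as a block, where the call was lost (adjusted p = 0.051), and adjusted p = 0.30 with an estimated correlation. Of glycolysis genes 0 of the 20 members tested differed upward, 2 downward and 18 did not pass, or 0 and 8 adjusted over the list alone (camera adjusted p = 1.8e-06, median log2 change -0.18). The median was -0.13 with slide as a block, and adjusted p = 0.21 with an estimated correlation. With COMB, ADAM19 (1.44 ± 0.11) and NGEF (0.90 ± 0.086; 0.62 and not called as the mean of all probes) differed upward, and CACNG6 (-1.33 ± 0.11), SGK1 (-1.30 ± 0.098) and AOX1 (-1.04 ± 0.097) downward, with a largest adjusted p of 0.00021. With slide as a block CACNG6 was at -1.50 and AOX1 at -1.53, both not called. Of glucocorticoid-induced genes 0 of the 21 members tested differed upward, 4 downward and 17 did not pass, or 0 and 9 adjusted over the list alone (camera adjusted p = 1.2e-09, median log2 change -0.28), including DUSP1 (-0.97 ± 0.11). The median was -0.29 with slide as a block, and adjusted p = 0.070 with an estimated correlation. Limma called 244 genes for GCRA (89 upward, 155 downward) and 201 for COMB (71 upward, 130 downward), and 4.4e2 and 341 with slide as a block. When single samples were left out the GCRA count was 148 without FBS replicate 3, 161 without GCRA replicate 1, 160 without GCRA replicate 2, 152 without shBRG1 FBS replicate 3, 147 without shBRG1 GCRA replicate 2, 142 without shBRG1 GCRA replicate 3 and 140 without GCRA replicate 3. The COMB count was 1.1e2 without FBS replicate 3, 1.2e2 without COMB replicate 1, 116 without COMB replicate 3, 120 without shBRG1 FBS replicate 3, 126 without shBRG1 COMB replicate 1 and 127 without shBRG1 COMB replicate 3.

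**Figure D3:**
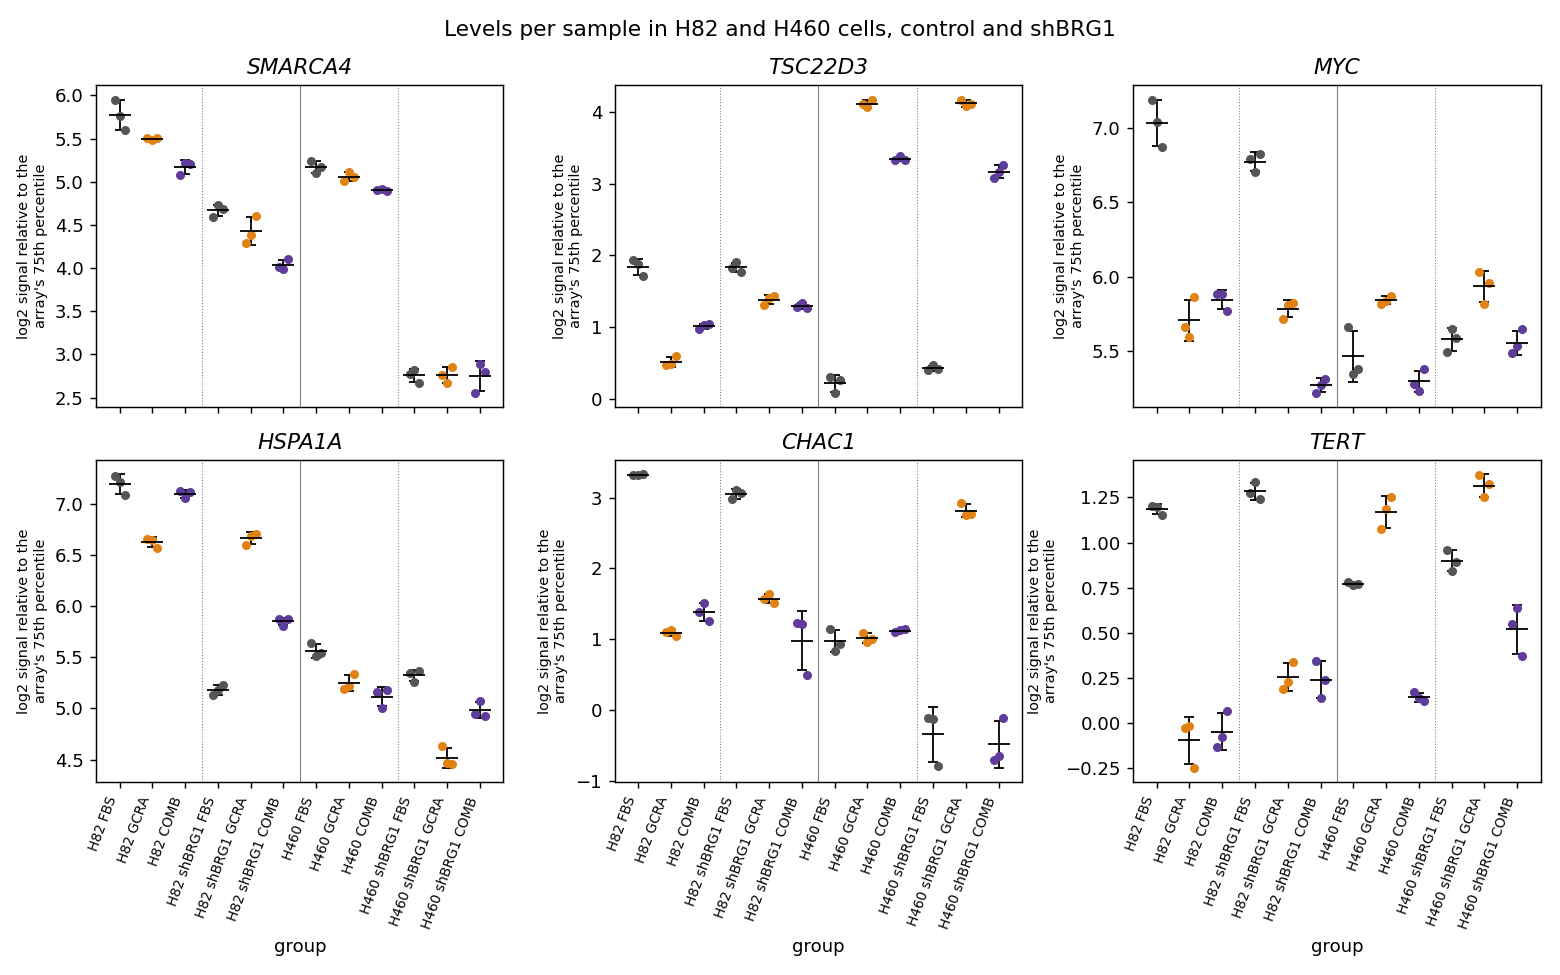
Levels of 6 genes (y axis, log2 signal relative to the array's 75th percentile) in each group of H82 and H460 control and shBRG1 cells (x axis). Points are samples and bars the mean ± SD of n = 3 per group, and CHAC1 rose with GCRA only in H460 shBRG1 cells among these 4 cell groups, by 3.17 ± 0.17.

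The shBRG1_2 cells gave the treatments again on another array design, without control cells. In H82 shBRG1_2 cells the pancreatic elastase genes CELA3B (7.21 ± 0.14) and CELA3A (7.15 ± 0.12) rose most with GCRA and CBLN4 (-4.84 ± 0.082) and DIAPH2-AS1 (-4.80 ± 0.099) fell most. The same 4 led with COMB (6.60, 6.55, -4.44 and -4.84). MYC target genes fell with both, with 0 up and 30 down of 30 in GCRA (camera adjusted p = 4.2e-14, median log2 change -0.75) and 0 up and 30 down of 30 in COMB (camera adjusted p = 4.1e-14, median log2 change -0.78). For GCRA the median was -0.75 with slide as a block, and adjusted p = 0.18 with an estimated correlation. For COMB the median was -0.83 with slide as a block, and adjusted p = 0.18 with an estimated correlation. MYC fell as well (-1.54 ± 0.050 and -1.60 ± 0.050). In H460 shBRG1_2 cells CYP26A1 (8.76 ± 0.12) and STRA6 (6.54 ± 0.19) rose most with GCRA and IL6 (-4.74 ± 0.10) and CXCL8 (-4.54 ± 0.070) fell most. With COMB CYP26A1 rose by 10.52 ± 0.13 and STRA6 by 7.90 ± 0.21, and the germ cell gene DAZL fell (-4.60 ± 0.12). Cell cycle genes fell, with 0 up and 27 down of 30, or 0 and 28 adjusted over the list alone in GCRA (camera adjusted p = 2.2e-14, median log2 change -0.85) and 0 up and 29 down of 30 in COMB (camera adjusted p = 6.2e-18, median log2 change -1.53). For GCRA the median was -0.86 with slide as a block, and adjusted p = 0.21 with an estimated correlation. For COMB the median was -1.51 with slide as a block, and adjusted p = 0.17 with an estimated correlation. With COMB AURKB fell (-2.43 ± 0.13). Glucocorticoid-induced genes rose, with 18 up and 0 down of 21 in GCRA (camera adjusted p = 1.9e-15, median log2 change 1.86) and 19 up and 0 down of 21 in COMB (camera adjusted p = 2.5e-15, median log2 change 2.10). With GCRA the median was 1.90 with slide as a block, and adjusted p = 0.16 with an estimated correlation. With COMB the median was 2.04 with slide as a block, and adjusted p = 0.17 with an estimated correlation. Limma called 11885 genes in H82 with GCRA (4844 up, 7041 down) and 12080 with COMB (5051 up, 7029 down). In H460 it called 7160 (3265 up, 3895 down) and, with n = 2 for COMB, 8856 (3926 up, 4930 down). With slide as a block the counts were 11846, 11883, 9337 and 10948. The H82 counts with normexp background correction were 8983 up and 6559 down for GCRA and 8304 up and 6455 down for COMB.

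Among the drug targets, MYC and the remodelling ATPases, named in every case, MYC was called down with GCRA in 2 of 5 control lines and up in 1, and with COMB against FBS down in 3 and up in 0. With COMB it fell in H82 (-1.19). NR3C1, the glucocorticoid receptor gene, was called up with GCRA in 2 lines, for example in H82 (0.67 ± 0.15), and down in 0; with COMB these counts were 2 and 1, with a fall in H1299 (-0.85 ± 0.11). RARA was called up with GCRA in 2 lines, for example in H82 (0.90 ± 0.080), and down in 1, and with COMB up in 2 and down in 0. RARB was called up with GCRA in 2 of 3 lines that tested it, for example in A549 (0.76 ± 0.076), and down in 0; with COMB it was called up in 3 of 3. DNMT1, the maintenance DNA methyltransferase gene, was called down with GCRA in 1 line and with COMB in 2, namely A549 (-0.96 ± 0.10) and DMS114 (-0.70 ± 0.091), and up in 0 lines with GCRA and 0 with COMB. SMARCA4 was called down in 2 of 5 lines with GCRA and 4 with COMB, and up in 0. SMARCA2, which encodes the alternative ATPase of the complex, was called up in 1 and down in 1 of 4 lines that tested it with each treatment. It was higher in shBRG1 than in control H82 cells in FBS (0.72 ± 0.13), but at 0.46 and not called with slide as a block, and was at -0.16 ± 0.15, not called, in H460. The list of drug target and MYC network genes was called by camera in 0 of 29 comparisons, with 0 at an unadjusted p under 0.05 and 0 with an estimated correlation.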

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

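Of the tests in this part, those of slide in H1299 alone, of NR3C1 levels and of starting levels in H82 were chosen after the result was seen. The results below were listed because a response differed between shBRG1 and control cells by the interaction test, or because lines moved in opposite directions.

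The GCRA interaction called 4507 genes in H82 and 244 in H460, and the COMB interaction 3397 and 201. For GCRA in H82 the named genes were HSPA6 (3.42), RARB (3.15), STMN2 (3.02), RFPL2 (3.0), HSPA1A (2.05), RFFL (-2.39) and RBP4 (-3.28), with list medians of 0.87 for heat shock, -0.48 for cholesterol synthesis and -0.23 for glycolysis genes. For GCRA in H460 they were CHAC1 (3.12), JDP2 (1.90), NGEF (1.45), SESN2 (1.34) and SGK1 (-1.22), with 0.33 for NF-kB, 0.11 for heat shock, -0.14 for glucocorticoid-induced and -0.18 for glycolysis genes. For COMB in H82 they were HK2 (-1.36), CXCR4 (-2.35), RAB17 (-2.39), RFFL (-2.42), IGF1 (-2.52) and LRRC17 (-3.42), with 0.47 for heat shock, 0.24 for MYC target, -0.36 for cholesterol synthesis and -0.56 for glycolysis genes and -0.86 for blood, endothelial and stromal markers. For COMB in H460 they were ADAM19 (1.44), NGEF (0.90), DUSP1 (-0.97), AOX1 (-1.04), SGK1 (-1.30) and CACNG6 (-1.33), with -0.28 for glucocorticoid-induced genes. With GCRA, TSC22D3 moved by -1.33 in H82 and by 3.90 in H460 and 4.0 in A549, and MYC target genes had a median of 0.18 in H1299, -0.55 in H82 and -0.75 in A549. These differences between lines were not tested. With an estimated correlation the calls of all lists in this paragraph were lost (adjusted p from 0.070 to 0.49), except heat shock genes for GCRA in H82 and NF-kB genes for GCRA in H460. With slide as a block the latter (0.18, adjusted p = 0.14) and glucocorticoid-induced genes for GCRA in H460 (-0.011, 0.051) were lost, as were AOX1 and CACNG6 (adjusted p = 0.44 and 0.057). As the mean of all probes HSPA6 was at 1.06 and NGEF for COMB at 0.62, both not called. In H1299 1 of 30 MYC target genes was called up.

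Other ways of splitting the samples were counted over genes with a value on every array. The 24 comparisons of 3 samples with 3 have 10 splits each, too few for a share under 0.05, and the real one was the 1 split with as many genes. Their real counts ran from 574 to 12075. The highest other split called at most 11 genes in 21 of them, 4.4e2 for shBRG1 in H460 in FBS (real count 1601), and 70 and 620 for GCRA and COMB in H460 shBRG1 cells (4818 and 6854). For the interactions 100 of 200 splits were drawn. For GCRA in H82 1 split was as large (real count 4501, highest other 4067), and for GCRA in H460 5 (244, 2574). For COMB these were 7 in H82 (3398, 9400) and 6 in H460 (200, 2418). In every split above the real count (4, 6 and 5) the construct was turned around in 1 treatment only. Its own difference then enters the interaction, so the splits drawn cannot decide on chance for any interaction.

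GCRA called fewer genes in DMS114 and H1299 than in the other control lines. Larger replicate spread was argued against for DMS114, not H1299, with median standard errors 0.761 and 1.2 times the highest of the other 3 lines. Slide was argued against for DMS114, where 1947 genes were called with slide as a block and at least 5675 in the other 3. For H1299 the count with slide as a block was 30 with 2 residual degrees of freedom, which cannot tell. NR3C1 in FBS was lower in these lines than in the other 3, with H1299 at -0.31 relative to H460 (SD 0.182 in H1299, which was measured in another run), so a lower receptor level may contribute as a hypothesis, and a difference between lines other than this was not tested.

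The GCRA response of H82 cells differed between shBRG1 and control cells. Slide was argued against, since 4594 genes were called with slide as a block and 4507 without. Signal near background was argued against, since among genes well above background on every array 22.4% were called, and 20% among all. Of the genes called, 62.6% differed less between the constructs in GCRA than in FBS (1924 were called in FBS only, 1046 in GCRA only). So a difference of starting levels that treatment removes may take part. The bounds for it (75% with it, 50% without) were set, not estimated, and cannot decide. The planned test, of all genes that differed between the constructs (6100 in GCRA, 7866 in FBS), argued against it. It was replaced after its result was seen, as most of those genes were not called here. Starting levels stay open, as does an effect of lower SMARCA4 or any other difference between the cells. Only 1 construct had control cells on its design.

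Rises of at least 2-fold outnumbered falls with COMB against GCRA in control cells. Signal near background was argued against, since this held in 5 of 5 lines among genes well above background on every array, with 285 against 12 in H82 and 203 against 44 in DMS114. Scaling of the arrays was argued against, since it held in 5 of 5 lines with quantile normalization, with 500 against 48 and 378 against 89. Release of germline and cancer-testis genes may take part, as the list was called upward in 5 of 5 lines (3 of 5 with an estimated correlation), but it held only a few of the genes that rose. Whether Aza, SAHA or both are needed stays open, as no sample had only one of them.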

How the results depend on the processing

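All alternatives were planned, so none was chosen after a result was seen. Directions held for the named results except MGAT5B for COMB in H1299, which was at 0.077 and not called as the mean of all its probes. The counts moved by over 1.5 times mainly without the filter on dim probes, with slide as a block and without single samples; the cause was not tested unless stated. Of the 29 gene counts, 28 stayed within 1.5 times with normexp background correction, 29 with quantile normalization, 29 with the mean of all probes, 22 with slide as a block, 21 without the filter, 27 with the replicate block and 27 with the series matrix, and all 26 outside H1299 did in one fit over the run. Without the filter, which adds dim genes to the adjustment, the counts were 89 for GCRA in DMS114, 202 in H1299, 3667 for COMB in DMS114, 1811 and 2398 for COMB against GCRA in A549 and DMS114, 998 for shBRG1 in H460 in FBS, and 94 and 91 for the GCRA and COMB interactions in H460. With slide as a block they were 1947 and 30 for GCRA in DMS114 and H1299, 2816 for COMB in H1299, 5330 and 1495 for COMB against GCRA in A549 and H1299, and 4.4e2 and 341 for the H460 interactions. In H1299 that fit leaves 2 residual degrees of freedom. With the replicate block the H460 interactions called 146 and 125 genes. From the series matrix GCRA in DMS114 called 321 and the COMB interaction in H460 1.2e2, and with normexp background correction the GCRA interaction in H460 called 156. When each sample was left out in turn (fewer samples; a lone sample left in a group was assumed to vary like the other groups), the counts ran from 125 to 873 for GCRA in DMS114, 206 to 1168 in H1299, 2058 to 2575, 1909 to 2798, 2917 to 4806 and 2686 to 3220 for COMB against GCRA in H460, A549, DMS114 and H1299, 1052 to 1825 for shBRG1 in H460 in FBS, and 140 to 274 and 1.1e2 to 234 for the GCRA and COMB interactions in H460. The other counts stayed within 1.5 times without any 1 sample. The contrasts of line types called 0 genes with limma under each alternative run for them (normexp background correction, quantile normalization, no filter, mean of all probes, series matrix and leaving out each line), with 4.6e2 to 2.3e3 genes at an unadjusted p under 0.05, and the exact p for their response sizes stayed between 0.40 and 1.

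The median of all genes moved by up to 0.177 with normexp background correction (over 0.1 in 3 comparisons), 0.123 with quantile normalization and 0.107 with the series matrix (1 comparison each), all largest in shBRG1_2 cells. For 236 values of named genes, 3387 of 3438 alternatives kept the direction and side of the threshold and 1 reversed, with a change for 18 values under some alternative. Besides those in the report, the calls of MGAT5B in H1299 (normexp background correction, no filter and slide as a block) and, in one fit over the run, of AOX1 and CACNG6 for the COMB interaction in H460 and SMARCA2 for shBRG1 in H82 were lost. So was that of MANSC4 in DMS114 under every alternative but leaving out FBS 2, and that of JUN in A549 with the series matrix, without the filter, with the replicate block and in one fit over the run. S100P was called down in H82 in one fit over the run. For 83 named list results 73 alternatives did not, with 0 reversed, and 59 of the lost calls were lost with an estimated correlation. In one fit over the run those of NF-kB genes for GCRA in A549 (adjusted p = 0.097), for shBRG1 in FBS (0.50) and the GCRA interaction (0.072) in H460, were lost, as was that of glucocorticoid-induced genes for GCRA in H82 (0.051) with the mean of all probes. Of 174 response sizes 92 left the range without single samples. Residuals of samples with the same replicate number had r as low as -0.675 in H82 and -0.116 in DMS114, so numbers were not used as pairs. In DMS114 their median r was 0.342 (-0.153 for others), and 7 of 9 samples were most alike to one of these. For samples of 1 slide it was 0.372 in H82, 0.348 in H460, 0.342 in DMS114 and 0.019 in H1299. In DMS114 these shared numbers, so slide and pairing cannot be separated. The 2 arrays of the repeated extract differed by an SD of 0.858, against 0.636 to 0.806 between other arrays of its group. Signal over background limits genes near it, whose folds are bounds, and at least 50.4% of probes were well above it on every array.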
